A study of Rattus norvegicus with 79 samples.

How the data were processed

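RNA from the hippocampus of 79 rats was measured on Affymetrix rat arrays after 2 rounds of amplification, with 1 array per animal per the labels. The intensity values were made by the authors with MAS5, per the submitters' processing notes, which give no version, and were deposited on a linear scale with 1 value per probe set. The 2% trimmed mean of every array lay between 500.03 and 500.12, and no column was left without a sample. For arrays the depth is not a count, and their number limits the precision. The labels name the dentate gyrus as the source, while the extraction protocol describes a punch of the CA1 cell layer.

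Of 15923 probe sets, 57 controls were left out. The platform annotation gives 1 gene for 12783 probe sets, several for 312 and none for 2771. Symbols were updated through the gene identifier for 12748 probe sets and through the accession for 2, and 33 were kept as annotated. Signals below 12.2, the percentile 5 of the table, were raised to that floor, which held for 0.007% of the values kept, and log2 was taken. Probe sets under the percentile 40 of mean log2 signal were left out, which kept 9520 probe sets and 7049 genes.

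Samples were grouped by age, training and learning class as the labels give them. Of the 7 comparisons, aged against young used age with training as a covariate, unimpaired against aged controls used a difference of 2 groups, and the other 5 used group means with contrasts. Each was fitted with limma 3.58.1 in R 4.3.3, with statmod 1.5.0, and moderated tests (two-sided) were adjusted by Benjamini and Hochberg at 0.05. The gene lists, 23 in number, were written before the data were examined, as were the groups, the comparisons, the naming rule and a first set of alternatives. They cover dentate granule, CA1 pyramidal, and CA3, CA2 and mossy cell markers, immature neuron, progenitor and cell cycle, activity-dependent early, microglia and phagocyte, MHC and interferon, astrocyte, myelin and oligodendrocyte, endothelial and mural, meningeal and matrix, choroid plexus and GABAergic interneuron genes. Also covered are glutamate receptor and postsynaptic, presynaptic vesicle, oxidative phosphorylation, heat shock and chaperone, glucocorticoid-responsive, cholesterol synthesis, blood, neuropeptide and trophic factor, and cytosolic ribosomal protein genes. Lists with at least 5 genes were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, the one of highest mean signal.

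The genes named are those with 1 gene per probe set and a symbol that is not a predicted locus only. For aged against young these are up to 12 genes in each direction with the largest differences among those that passed, for every other comparison the 10 genes in each direction with the smallest p, and for each list up to 4 members with the smallest p. Permutation tests used 1e+05 resamples, bootstrap intervals 1000 resamples of animals at 95%, and splits of the samples 100 draws.

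The alternatives tried were quantile normalization, centring on the percentile 75, no filter and a filter at the percentile 60, a floor at the percentile 20, 16 added to each signal in place of a floor, array weights, the 3 runs of animal codes as a block, the Gapdh 3' over 5' ratio or CA1 and choroid plexus scores as covariates, an unadjusted p of 0.005, other sets of animals or controls, and each animal of a group of 5 or fewer left out in turn. For the lists, the correlation was also estimated from the data, and all probe sets were used. The runs are taken from the numbers of the animals and are not called batches in the labels, and 4188 of the 9520 probe sets differed between them. After the data were seen, 6 limits on the median correlation of an array with the others, the log2 median signal as a covariate, weights fitted gene by gene, pairs of settings and, for unimpaired against impaired learners only, the beta-actin 3' over 5' ratio as a covariate were added; the limit of 0.8 was picked after the calls under all 6 were seen. Within-run values were also computed after the data were seen.

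The code was tested on the real arrays, shuffled once among the groups of each comparison, with 100 probe sets changed by 0.5 and 100 by 1.0 on the log2 scale. The shuffle crossed the runs of animal codes, so the uneven runs were not kept in this self-test. Of those changed by 1.0, 100% were recovered for age, 88% and 80% for unimpaired learners against controls and against impaired learners, and 33% to 50% for the other 4 comparisons. Of those changed by 0.5, 45%, 30% and 16% were recovered for the first 3 comparisons and 0% to 3% for the others. Among unchanged probe sets, 9 passed for aged swimming animals, 4 for unimpaired learners against controls and 1 for young hidden platform animals. In each of the other comparisons 0 passed.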

Results

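The series measured RNA of the hippocampus in 79 male Fischer rats, with 1 Affymetrix array per animal, after training in the Morris water maze. In this task a rat learns the place of a platform hidden under water. The 53 aged rats were 24 months old and the 26 young rats were 3 months old. Among the aged rats trained on the hidden platform, 14 were graded as unimpaired learners, 14 as intermediate and 10 as impaired. A further 5 aged rats were trained with a visible platform, 7 were yoke controls that swam without a platform and 3 stayed in their cages. The young rats comprised 9 trained on the hidden platform, 5 trained with the visible platform, 5 yoke controls and 7 cage controls.

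The labels name the dentate gyrus as the tissue, while the extraction protocol describes a punch of the CA1 cell layer. Prox1, a transcription factor of dentate granule cells, had a mean log2 signal of 11.72 ± 0.50 (SD, n = 79), at percentile 97.8 of all probe sets. Wfs1, an endoplasmic reticulum protein used as a marker of CA1 pyramidal cells, stood at 10.26 ± 0.76 (SD, n = 79), at percentile 89.1. The marker lists overlapped among the members kept. Granule cell markers ran from Ncald (percentile 99) to Trpc6 (49.8), and CA1 markers from Itpka (94.1) to Dcn (40.9). Markers of the CA3, CA2 and mossy cell list ran from Pcp4 (98.7) to Fgf2 (43.6). Levels of different probe sets are not on a common scale, and Prox1 and Wfs1 were picked after their values were seen. These levels do not tell which tissue was taken.

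Arrays differed in quality. The median signal of an array lay between 197.35 and 406.9 while trimmed means lay between 500.03 and 500.12, and the number of arrays limits the precision of every value. The first principal component held 29.26% of the variance. The sign of a component is arbitrary, and the size of its correlation with the log2 median signal was 0.905 by Pearson's r and 0.977 by Spearman's rho (permutation p = 1e-05 for each, the smallest that the resampling can give). Without the 2 arrays farthest from the median, r was 0.886. Within the 3 runs of animal codes, r was 0.813, 0.988 and 0.978, and this was the only relation across arrays that was computed. Both measures come from the same log2 signals, and arrays were not centred for the component. The relation is thus largely set in advance, and its p is no separate evidence on quality. The median correlation of the array of young cage animal D034 with the other arrays was 0.071, and 14 arrays, 8 aged and 6 young, lay under 0.8. Of these 14 arrays, 7 were in the third run of animal codes, which holds 19 arrays. The log2 ratio of 3' to 5' signal of Gapdh, used as a sign of RNA integrity, was 2.22 ± 0.89 (SD, n = 53) in aged and 2.15 ± 1.15 (SD, n = 26) in young animals. The RNA had been amplified in 2 rounds, and the ratio does not tell amplification from integrity. The permutation p of the difference between the ages was 0.781 (two-sided), and 6 such tests of array measures had adjusted p of 0.299 to 0.781.

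**Figure D1:**
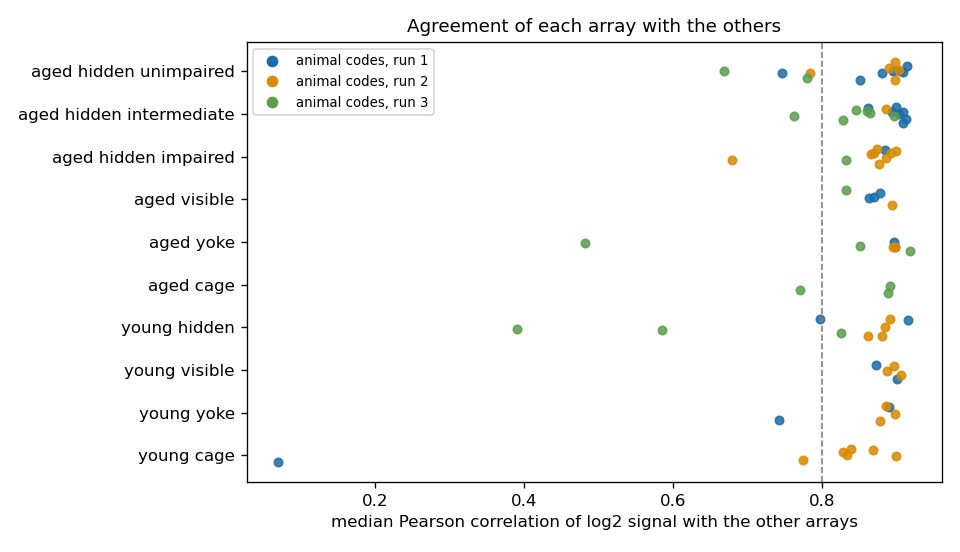
Median Pearson correlation of each array's log2 signals with the other arrays (x axis), by group (y axis), with colours for the 3 runs of animal codes. Each point is 1 animal, the dashed line marks 0.8, and the array of young cage animal D034 lies at 0.071.

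The first comparison asked which transcripts differ between aged and young animals, with training as a covariate. Aged animals had higher signals of 2 astrocyte genes. Gfap, the intermediate filament of astrocytes, rose by 0.68 ± 0.15 on the log2 scale (SE, 53 aged and 26 young), to 12.68 ± 0.34 (SD) from 12.00 ± 0.88 (SD), with 48 of 53 aged animals above the young median (adjusted p = 0.0192). S100b, a calcium-binding protein of astrocytes, rose by 0.55 ± 0.13 (SE, 44 of 53 animals, adjusted p = 0.0217). Slc17a6, the vesicular glutamate transporter VGLUT2, fell by 0.74 ± 0.16 (SE, 52 of 53 animals below the young median, adjusted p = 0.021). Sema3c, a secreted axon guidance protein, fell by 0.64 ± 0.13 (SE, 51 of 53, adjusted p = 0.0132), and Col4a5, a collagen chain of basement membranes, fell by 0.67 ± 0.14 (SE, 47 of 53, adjusted p = 0.0132).

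In total 34 of 9520 probe sets passed in limma, 27 higher and 7 lower in aged animals. Hipk2, a nuclear protein kinase, had the largest change of a named gene, 1.18 ± 0.24 (SE, 47 of 53 animals, adjusted p = 0.0132). Eeig1 rose by 0.89, Tiam1, an activator of the GTPase Rac, by 0.87, and Eps8l2, a regulator of actin, by 0.86. Tecpr1, a protein of autophagosome maturation, rose by 0.77, and the phosphatase Ptp4a3 by 0.73. Pla2g6, a phospholipase, rose by 0.73, although another probe set of this gene had a difference in the opposite direction. Ncdn, a neuronal cytoplasmic protein, rose by 0.73, and Plin4, a coat protein of lipid droplets, by 0.65. Cdh13, a cadherin anchored to the membrane by a lipid, rose in 3 probe sets by 0.61, 0.86 and 1.05. The ubiquitin ligase Marchf1 fell by 0.68, the transcription factor Patz1 by 0.42, the pseudokinase Trib2 by 0.41 and Ginm1 by 0.34. Mpeg1, a pore-forming protein of macrophages and microglia outside the naming rule and picked after its value was seen, rose by 0.39 ± 0.07 (SE, adjusted p = 0.00292).

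Without the 14 arrays of low correlation, 26 probe sets passed, 12 higher and 14 lower, of which 14 were among the 34. This setting was chosen after the data were seen, and 6 such limits gave from 6 to 47 probe sets. Of the 19 named genes, 8 then passed: Hipk2 (1.06), Eps8l2 (0.74), Cdh13 (0.83), Gfap (0.55), Slc17a6 (-0.74), Col4a5 (-0.58), Sema3c (-0.81) and Trib2 (-0.495). The other 11 named genes did not pass there, S100b (0.425) and Ncdn (0.60) among them, and Eeig1 (0.58), Tecpr1 (0.48), Ptp4a3 (0.39), Plin4 (0.42), Patz1 (-0.16) and Ginm1 (-0.21) moved by over 1.5 times. The third run held 3 young arrays, and 2 of those had correlations of 0.391 and 0.586. Within the 3 runs of animal codes, the difference was 0.90, 0.32 and 1.61 for Gfap, 0.54, 0.64 and 3.39 for Hipk2, and -0.96, -1.01 and -0.44 for Slc17a6. It was 0.26, 0.68 and 3.08 for Tiam1 and 0.04, 0.84 and 1.63 for Eps8l2. For Tecpr1 it was 0.80, -0.035 and 2.55, so the direction turned in the second run. Of the 34 probe sets, 34, 33 and 34 had the pooled direction within the 3 runs. They were chosen on these same arrays, so this agreement is largely set in advance and is no replication. The within-run values do not take training into account, and the 3 young arrays of the third run were all hidden platform animals. With the run as a block 87 passed, 28 of them among the 34. The block ended the calls of Eps8l2 (0.73, adjusted p = 0.0572), Marchf1 (-0.54, adjusted p = 0.0667), Trib2 (-0.315, adjusted p = 0.0872) and the Cdh13 probe set at 0.61 (0.52, adjusted p = 0.0727). The count was 13 without aged cage animal D099 and 57 without young yoke animal D023, 18 after quantile normalization and 1266 with array weights, of which 737 were higher. It was 1 in hidden platform animals alone, a probe set for which the annotation gives no gene, and 0 in the visible platform, yoke and cage animals alone by limma.

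**Figure D2:**
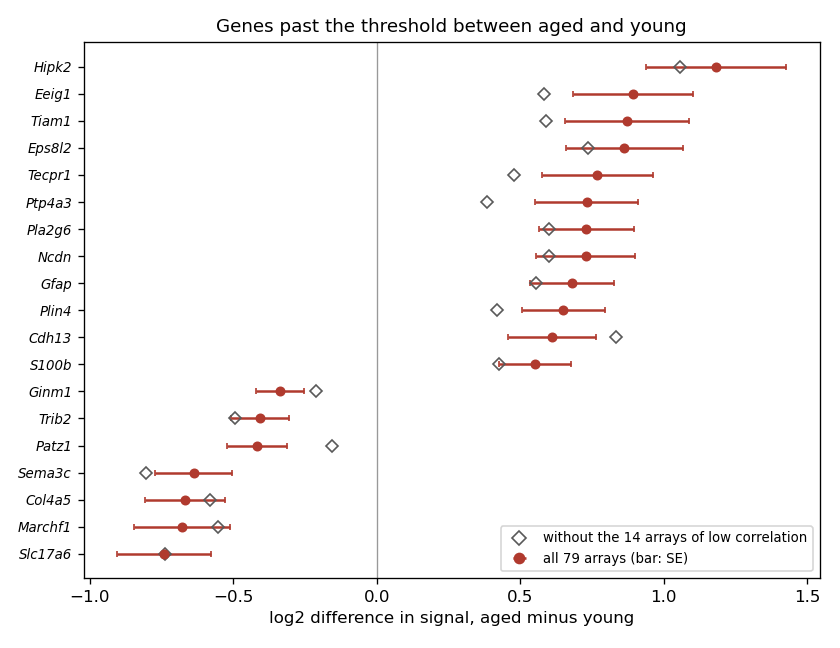
Log2 difference between aged and young animals (x axis) of the 19 named genes that passed (y axis). Each filled point is 1 gene over all 79 arrays with its SE, and each open diamond is the same gene without the 14 arrays of low correlation.

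Gene groups fixed before the data were examined were compared with all other genes by camera. The median difference of all probe sets was 0.046, so counts of members above 0 do not start from an even share. The list of cytosolic ribosomal protein genes rose in aged animals (adjusted p = 6.26e-10), and 37 of its 38 members had differences above 0, with a median of 0.28. Its adjusted p = 0.38 with an estimated correlation, and 8 alternatives gave 1.18e-09 to 0.38. No member passed over all probe sets and 11 passed adjusted over the list alone, with Rpl34 at 0.75 ± 0.19 (SE) and Rpl19 at 0.42 ± 0.12 (SE). Without the 14 arrays the median was 0.17, with Rpl34 at 0.49 and Rpl19 at 0.25. Relative to all genes, the mean of the list was higher by 0.20, 0.15 and 0.54 in the 3 runs of animal codes.

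The list of astrocyte genes rose (adjusted p = 0.000265), with 27 of 33 members above 0. Its adjusted p = 0.425 with an estimated correlation, in a range of 4.08e-05 to 0.425 over 8 alternatives. Gfap and S100b passed over all probe sets and 6 members passed adjusted over the list alone, among them Apoe, a lipid carrier, at 0.64 ± 0.17 (SE). The list of myelin and oligodendrocyte genes rose (adjusted p = 0.0158), with 28 of 35 members above 0, and adjusted p = 0.425 with an estimated correlation (0.00012 to 0.576 over 8 alternatives). No member passed over all probe sets and 3 passed adjusted over the list alone, among them Qdpr at 0.44 and Mbp, a main protein of myelin, at 0.45 ± 0.14 (SE). Without the 14 arrays the calls of the astrocyte (adjusted p = 0.16) and myelin (adjusted p = 0.576) lists ended, the median member differences went from 0.27 to 0.11 and from 0.21 to 0.07, and Mbp was at 0.24. Their means relative to all genes were 0.34, 0.09 and 0.48, and 0.21, 0.12 and 0.33, within the 3 runs.

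Presynaptic vesicle genes rose as a list (adjusted p = 0.00111), with 41 of 49 members above 0, and adjusted p = 0.425 with an estimated correlation (8.73e-05 to 0.522 over 8 alternatives). Only Slc17a6, which fell, passed over all probe sets; 4 members rose and 1 fell adjusted over the list alone, and Snap25, a protein of vesicle fusion, was at 0.54 ± 0.15 (SE). Glutamate receptor and postsynaptic genes rose as a list (adjusted p = 0.0366), with 43 of 60 above 0, and adjusted p = 0.425 with an estimated correlation (0.0301 to 0.425). No member passed over all probe sets and 3 passed adjusted over the list alone, with the AMPA receptor subunit Gria1 at 0.42 ± 0.13 (SE). Oxidative phosphorylation genes, which code for the respiratory chain, rose as a list (adjusted p = 0.00275), with 62 of 71 above 0 and adjusted p = 0.583 with an estimated correlation (7.6e-05 to 0.583). No member passed in either count, and Cox4i1 was at 0.49 ± 0.18 (SE). Each of these 3 calls ended without the 14 arrays. The median went from 0.20 to 0.08 for the presynaptic list, with Snap25 at 0.30, and from 0.17 to 0.03 for the oxidative phosphorylation list, while that of the glutamate receptor list stayed close, at 0.14 and 0.12. Their means relative to all genes within the runs were 0.20, 0.01 and 0.57, then 0.07, 0.06 and 0.17, then 0.29, 0.11 and 0.19.

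Endothelial and mural genes, which mark blood vessels, fell as a list (adjusted p = 0.00275), with 16 of 22 members below 0 and a median of -0.14. Their adjusted p = 0.225 with an estimated correlation (0.00213 to 0.225 over 8 alternatives). No member passed in either count, and Vcam1, an adhesion molecule, was at -0.44 ± 0.17 (SE). The progenitor and cell cycle genes fell as a list (adjusted p = 0.0369), with 12 of 17 members below 0 and adjusted p = 0.38 with an estimated correlation (0.00234 to 0.602). No member passed in either count, Pcna, a clamp of DNA replication, was at -0.16 ± 0.14 (SE), and the call ended without D034 (adjusted p = 0.0527) and without the 14 arrays, where the median of the list went from -0.09 to -0.01. Immature neuron genes were ranked lower than other genes by the test (adjusted p = 0.0487), while 12 of 24 members were below 0 and 12 above, with a median of -0.03 and adjusted p = 0.428 with an estimated correlation (0.0151 to 0.428). Sema3c passed over all probe sets, and Sema3c, Marcksl1 (-0.33) and Nrep (-0.44) passed adjusted over the list alone. Activity-dependent early genes were ranked lower than other genes (adjusted p = 0.0387), with 19 of 33 below 0, a median of -0.01 and adjusted p = 0.425 with an estimated correlation (0.0125 to 0.425). No member passed in either count, and Homer1, a postsynaptic scaffold protein, was at -0.40 ± 0.14 (SE). With the run as a block the immature neuron and early gene calls ended, at an adjusted p of 0.242 each. Within the 3 runs the means relative to all genes were -0.12, -0.26 and 0.05 for the endothelial, -0.26, -0.20 and -0.26 for the progenitor, -0.04, -0.06 and -0.07 for the immature neuron and 0.08, -0.09 and -0.11 for the early gene list.

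The other 12 lists tested did not pass in aged against young animals. Microglia and phagocyte genes had an adjusted p of 0.133, with 18 of 26 members above 0, and 2 of them, the lysozyme Lyz2 (0.55, and 0.22 without the 14 arrays) and the complement gene C1qa (0.51), passed adjusted over the list alone. The CA1 pyramidal list had an adjusted p of 0.086, with 1 member higher and 1 lower adjusted over the list alone, and the dentate granule list 0.378. Adjusted p was 0.298 for MHC and interferon genes, 0.0999 for meningeal and matrix genes, 0.378 for GABAergic interneuron genes and 0.0895 for glucocorticoid-responsive genes, of which Plin4 passed. It was 0.582 for heat shock and chaperone genes and 0.497 for neuropeptide and trophic factor genes. The 3 lists CA3, CA2 and mossy cell (0.819), choroid plexus (0.785) and cholesterol synthesis (0.828), were ranked lower by the test while their median differences were 0.05, 0.03 and 0.05. The blood list kept 1 gene, the haemoglobin gene Hbb, at 0.77 ± 0.26 (SE), and was not tested as a list.

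**Figure D3:**
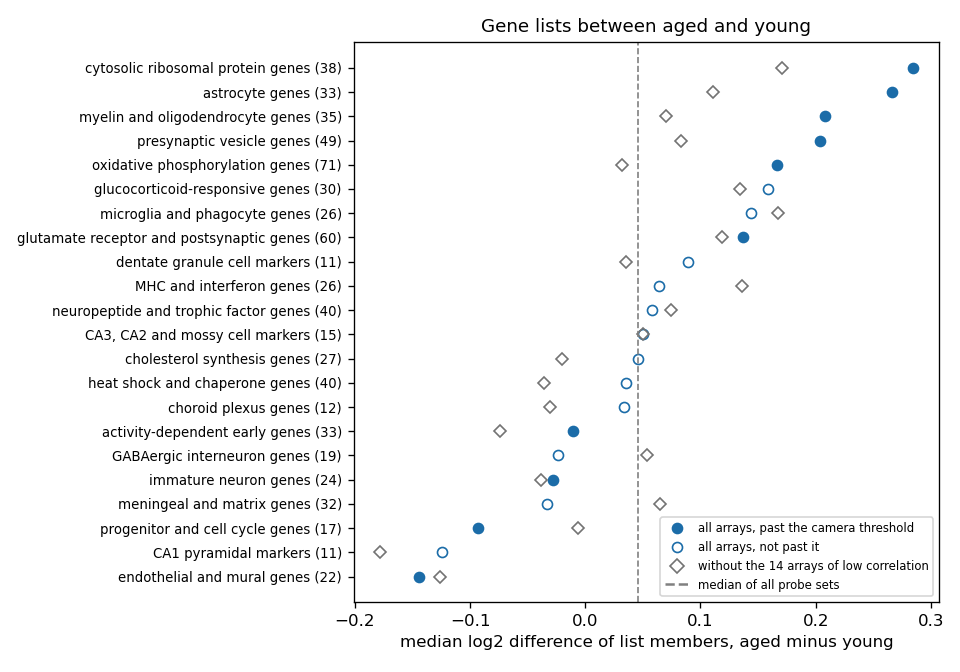
Median log2 difference between aged and young animals (x axis) of each gene list (y axis, number of genes in brackets). Each circle is 1 list, filled where it passed, diamonds are medians without the 14 arrays, and the dashed line is the median of all probe sets.

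The second comparison follows the supervised design of the series and asked what sets aged unimpaired learners apart from 25 aged controls, which were impaired learners and visible platform, yoke and cage animals. The genes with the smallest p did not pass. Scd, the enzyme that desaturates stearic acid, was at -0.65 ± 0.16 (SE, 13 of 14 unimpaired animals below the control median, adjusted p = 0.781), with -0.65, -0.64 and -0.75 within the 3 runs. Hdac5, a histone deacetylase, was at 0.57 ± 0.18 (SE, adjusted p = 0.968), and Map6, a stabiliser of microtubules, at 0.39 ± 0.12 (SE, adjusted p = 0.968), and without the 14 arrays these were 0.35 and 0.25. Among the gene lists none of 22 passed, and the smallest adjusted p was 0.248, for heat shock and chaperone genes, with 26 of 40 members below 0. The early gene list was ranked lower by the test while its median was 0.013.

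A single probe set passed in limma. The annotation gives no gene for it, so that it lies outside the naming rule and was picked after its value was seen. It fell by 0.78 ± 0.14 (SE), to 7.63 ± 0.47 (SD, n = 14) from 8.41 ± 0.40 (SD, n = 25), with an adjusted p of 0.0253 (0.000369 to 0.536 over 34 alternatives). At an unadjusted p under 0.05 there were 416 probe sets, against 476 by chance. No probe set passed after quantile normalization, with the run as a block or without a filter on dim probe sets, while 384 passed with array weights and 336 with weights fitted gene by gene.

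The third comparison set aged unimpaired against aged impaired learners, which were trained alike. No probe set passed in limma, although 1316 had an unadjusted p under 0.05 against 476 by chance. With the run as a block 513 did. The log2 ratio of 3' to 5' signal of beta-actin was 2.84 ± 0.82 (SD, n = 14) in unimpaired and 3.60 ± 0.96 (SD, n = 10) in impaired learners (permutation p = 0.0498, adjusted p = 0.299, two-sided). With this ratio as a covariate, chosen after the data were seen, 811 had an unadjusted p under 0.05 and 0 passed. Ntrk3, the receptor of neurotrophin 3, was at 0.75 ± 0.19 (SE, 14 of 14 unimpaired animals above the impaired median, adjusted p = 0.15), with 9.05 ± 0.50 (SD, n = 14) against 8.30 ± 0.56 (SD, n = 10). Grm3, a metabotropic glutamate receptor, was at -0.73 ± 0.20 (SE, 13 of 14, adjusted p = 0.219). Cntnap2, an adhesion protein of axons, was at -0.42 ± 0.11 (SE, 14 of 14, adjusted p = 0.15), Cd99l2 at -0.59 ± 0.13 (SE, 14 of 14) and Cyp8b1, an enzyme of bile acid synthesis, at 1.10 ± 0.26 (SE, 14 of 14). Unimpaired animals fell into the 3 runs as 7, 5 and 2 and impaired animals as 1, 8 and 1, so that differences are given for the second run alone, the only one with more than 1 impaired animal. In this run it was 0.69 for Ntrk3, -0.58 for Grm3 (over all animals -0.45 with the run as a block and -0.42 with the beta-actin ratio), -0.50 for Cntnap2, -0.58 for Cd99l2 and 0.64 for Cyp8b1.

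Myelin and oligodendrocyte genes were lower as a list in unimpaired learners (adjusted p = 0.00691), with 26 of 35 members below 0 and a median of -0.18, and -0.09 without the 14 arrays. Their adjusted p = 0.591 with an estimated correlation (0.00492 to 0.591 over 9 alternatives). The activity-dependent early genes were lower (adjusted p = 0.0337), with 21 of 33 below 0 and adjusted p = 0.417 with an estimated correlation (0.00405 to 0.417), and the nuclear receptor Nr4a3 was at -0.85 ± 0.26 (SE), and -0.53 without the 14 arrays. Heat shock and chaperone genes were lower (adjusted p = 0.0337), with 27 of 40 below 0 and adjusted p = 0.591 with an estimated correlation (0.0132 to 0.591). MHC and interferon genes were higher (adjusted p = 0.0337), with 20 of 26 above 0 and adjusted p = 0.591 with an estimated correlation (0.0292 to 0.591), and the interferon regulator Irf7 was at 0.49 ± 0.18 (SE), and 0.29 without the 14 arrays. Meningeal and matrix genes were higher (adjusted p = 0.0337), with 27 of 32 above 0 and adjusted p = 0.591 with an estimated correlation (0.0132 to 0.809), and the collagen gene Col18a1 was at 0.77 ± 0.24 (SE). Choroid plexus genes, markers of a neighbouring tissue, had a median of 0.32, with 10 of 12 above 0, and did not pass (adjusted p = 0.173, and adjusted p = 0.591 with an estimated correlation, 0.124 to 0.949 over 9 alternatives), while the median of the meningeal list was 0.25, and 0.16 without the 14 arrays. Of 9 alternatives, 8 kept the call of the myelin list, 7 that of the early gene list, 6 that of the heat shock list, 3 that of the MHC list and 2 that of the meningeal list. In these 5 lists 0 members passed over all probe sets in limma and 0 adjusted over the list alone. Counts of members above 0 do not start from an even share, as the median difference of all probe sets was 0.051. Within the second run the means relative to all genes were -0.15, -0.20, -0.10, 0.11 and 0.10 in the order given. With the log2 median signal as a covariate 4 of these calls ended, with the early gene list at an adjusted p of 0.0791, heat shock and MHC lists at 0.423 each and the meningeal list at 0.809. With the beta-actin ratio the calls of the MHC (adjusted p = 0.0639, median from 0.23 to 0.15) and meningeal lists (adjusted p = 0.179, median from 0.25 to 0.17) ended.

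The impaired group held 1 of the 14 arrays of low correlation and the unimpaired group 4. Without them Ntrk3 passed, in a setting chosen after the data were seen, with an adjusted p of 0.0378 (4.88e-05 to 0.897 over 35 alternatives). Array weights gave 2290 probe sets, 1470 higher and 820 lower, and weights fitted gene by gene 2192. Splits of the animals that traded learning class only within a run gave up to 4539 probe sets with array weights, so the 2290 are not given here as differences between learning classes.

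**Figure D4:**
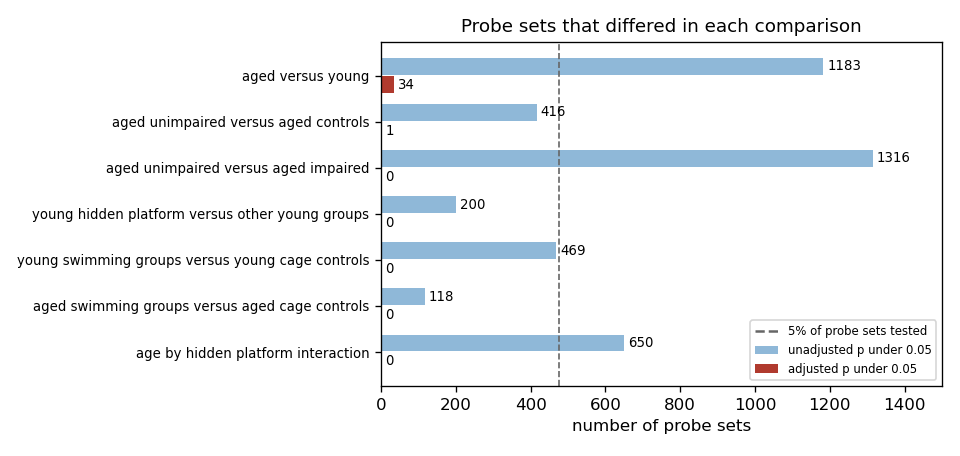
Number of probe sets (x axis) that passed in each comparison (y axis), in red at an adjusted p under 0.05 and in blue at an unadjusted p under 0.05. The dashed line is the number that chance gives, 476. The comparison of aged with young animals has 34 probe sets at the adjusted threshold and 1183 at the unadjusted one.

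The fourth comparison asked what differs between young hidden platform animals and the other young groups. Rgs16, a regulator of G protein signalling, was at 1.00 ± 0.24 (SE, 9 of 9 animals above the median of the others), with a limma adjusted p of 0.999, and at 0.85 and 0.69 within the first 2 runs. Klhl2, an adaptor of a ubiquitin ligase, was at -1.04 ± 0.31 (SE, 8 of 9), and the immediate early gene Nr4a1 at 0.55 ± 0.24 (SE). These were 0.605 for Rgs16, -0.45 for Klhl2 and 0.35 for Nr4a1 without the 14 arrays, and Klhl2 was at -0.505 with the run as a block. No probe set passed in limma, 200 had an unadjusted p under 0.05 and no gene list passed, with 0.0601 the smallest adjusted p, for ribosomal protein genes and for presynaptic vesicle genes. The third run held 3 hidden platform animals and no other young animals, so it gives no difference. In the self-test 33% of changes of 1.0 on the log2 scale and 0% of changes of 0.5 were found at these sizes.

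The fifth comparison set the young animals that swam against young cage controls. All probe sets had a median difference of 0.09 here, so counts of members above 0 do not start from an even share. Meningeal and matrix genes were lower as a list in the animals that swam (adjusted p = 2.14e-06), with 24 of 32 members below 0. Their adjusted p = 0.168 with an estimated correlation (6.05e-07 to 0.168 over 8 alternatives), with the growth factor Igf2 at -0.65 ± 0.23 (SE), -0.30 without the 14 arrays, and Mgp, an inhibitor of calcification, at -0.78 ± 0.28 (SE). Microglia and phagocyte genes were lower (adjusted p = 0.0165), with 16 of 26 below 0 and adjusted p = 0.385 with an estimated correlation (0.0128 to 0.385), and Csf1r, a receptor of microglia, was at -0.56 ± 0.23 (SE). Oxidative phosphorylation genes were higher (adjusted p = 2.14e-06), with 67 of 71 above 0 and adjusted p = 0.75 with an estimated correlation (3.08e-06 to 0.75), and ribosomal protein genes were higher (adjusted p = 0.0339), with 33 of 38 above 0 and adjusted p = 0.75 with an estimated correlation (0.0432 to 0.802). In these 4 lists no member passed over all probe sets in limma or adjusted over the list alone. The array of D034 was 1 of the 7 cage controls. Without it the adjusted p was 0.00047 for the meningeal list, 0.22 for the microglia list, 0.577 for the oxidative phosphorylation list and 0.802 for the ribosomal list. Leaving out all 14 arrays moved the medians from -0.27 to -0.20, from -0.17 to -0.13, from 0.43 to 0.04 and from 0.31 to 0.05 in the same order. In the second run, the only run with enough cage controls, the means relative to all genes were -0.28, -0.16, 0.01 and -0.03 in the same order.

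No probe set passed in limma for the young animals that swam, 469 had an unadjusted p under 0.05, and the smallest adjusted p was 0.695. Smarcb1, a subunit of a chromatin remodelling complex, was at 1.53 ± 0.40 (SE, 17 of 19 animals above the cage median), and Pdpn, a surface glycoprotein of meninges and choroid plexus, at -0.61 ± 0.19 (SE, 18 of 19 below it). In the second run these differences were 1.24 and -0.60.

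The sixth comparison set the aged animals that swam against the 3 aged cage controls, all of which were in the third run. Sirt2, a deacetylase abundant in oligodendrocytes, was at 1.45 ± 0.41 (SE, 47 of 50 animals above the cage median, adjusted p = 1.00) and at 0.98 within the third run. Tbcb, a cofactor of tubulin folding, was at 1.13 ± 0.30 (SE) and passed, as the only probe set, without aged cage animal D098. Aged cage animal D099 was among the 14 arrays of low correlation, and without them Sirt2 was at 0.535 and Tbcb at 0.27. Oxidative phosphorylation genes were higher as a list (adjusted p = 1.96e-05), with 58 of 71 above 0 and adjusted p = 0.789 with an estimated correlation (2.98e-07 to 0.906). Of its members 0 passed over all probe sets in limma and 0 adjusted over the list alone, with Ndufb10 at 0.57 ± 0.26 (SE). Without the 14 arrays the adjusted p of the oxidative phosphorylation genes was 0.0566, while their median was 0.16 against 0.15 with all arrays. With the run as a block the direction of this list turned, with an adjusted p of 0.906, and its mean relative to all genes within the third run was -0.02. No probe set passed in limma and 118 had an unadjusted p under 0.05, while weights fitted gene by gene gave 4, which were Ube3b, Stk17b, Cyp51 and 1 probe set without a gene in the annotation, picked after their values were seen.

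The seventh comparison tested whether the difference between hidden platform and other animals was itself different in aged and young rats. No probe set passed in limma and 650 had an unadjusted p under 0.05. Rgs16 had the smallest p, with a difference of -1.35 ± 0.30 (SE, adjusted p = 0.259, 0.0788 to 1 over 42 alternatives). With groups weighted equally, its mean was 8.25 in young hidden platform animals and 7.24 in the other young groups, and 7.83 in aged hidden platform animals and 8.18 in the other aged groups. Young hidden platform animal D080 stood apart at 9.78, and without it the difference was -1.16. Klf4, an early response transcription factor, was at -0.82 ± 0.28 (SE, adjusted p = 0.721) and Sirt2 at 1.40 ± 0.39 (SE, adjusted p = 0.721). Leaving out the 14 arrays gave -0.72 for Rgs16, -0.49 for Klf4 and 0.30 for Sirt2, which was at 0.83 with the run as a block. No gene list passed, and the smallest adjusted p was 0.0595, for myelin and oligodendrocyte genes, of which 1 higher and 1 lower member passed adjusted over the list alone.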

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

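All tests in this part were chosen after their results were seen, except the test of tissue scores for age, the test of arrays for the learning classes with array weights and the splits within runs, of which those for age and for unimpaired learners against controls were added once all other results were known.

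A sample far from the rest of its group was found in 5 of 28 tests of array measures and 7 of 60 tests of gene values. Groups of 14 and of 3 animals were not tested. For independent normal values chance alone gives about 1 in 20 tests. The genes were named for their small p in comparisons that use the same arrays, so that rate does not hold for them. Each value below is the gap to the nearest sample divided by the range of the group. For the median correlation with other arrays it was 0.695 for aged impaired animal D047 (0.679 against 0.833 to 0.9), 0.845 for aged yoke D093 (0.482 against 0.851 to 0.919), 0.85 for young cage D034 (0.071 against 0.775 to 0.899) and 0.876 for young yoke D024 (0.742 against 0.878 to 0.897). For the log2 Gapdh 3' over 5' ratio it was 0.827 for aged visible D096 (2.85 against 0.923 to 1.257).

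Among genes, young cage D034 stood apart for Chmp7 (0.575, with 7.47 against 8.81 to 9.81), Ifitm2 (0.58, with 10.48 against 8.34 to 9.24) and Cgnl1 (0.719, with 10.38 against 7.85 to 8.56). Young hidden platform D077 stood apart for Rnh1 (0.598, with 4.46 against 6.52 to 7.90) and Paxip1 (0.645, with 7.55 against 8.29 to 8.69), and D080 for Rgs16 (0.53, with 9.78 against 7.55 to 8.60). Aged impaired D083 stood apart for Mob2 (0.58, with 6.27 against 7.73 to 8.78). No explanation of these single values was tested.

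The first pattern is the set of 34 probe sets that passed between aged and young animals. Of 100 splits of the samples, the real one included, 2 gave as many. The only other split with any calls gave 1356 against the real 34, and why it did was not tested. With animals traded only within training groups and runs, 1 of 100 splits (the real one) gave as many and the highest other gave 2. No run held cage animals of both ages, so cage animals, D034 among them, kept their real age there. Both counts argue against chance but do not exclude it. Low array quality as the whole source is argued against only narrowly. The median ratio of the differences without the 14 arrays to those with all arrays was 0.818 (0.544 to 0.992). Its bound of 0.5 was set after the results were seen. The probe sets were chosen on these same arrays, so such ratios say nothing on chance. Uneven runs alone are argued against as the whole source, with a ratio of 1.015 with the run as a block (0.843 to 1.056). Array quality and runs were not tested together by such a ratio. With the block and the limit of 0.8 at once, fewer probe sets passed than with either alone. With the CA1 and choroid plexus scores the ratio was 1.004 (0.894 to 1.075). The tissue taken is itself not settled, so the CA1 score may not measure stray tissue and this ratio does not decide on the dissection. Age itself may be the source and stays open, as it was not tested apart from the groups.

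The second pattern is the higher ribosomal protein list in aged animals. Its mean relative to all genes was 0.241 (0.078 to 0.412 over resampled animals). Without D064 and D080, the 2 young arrays that lower it most when left out together, it was 0.166 (0.035 to 0.306), an interval that holds 0.121, the bound set for a shift made by few arrays, so a few arrays as its source stay open. Without the 14 arrays it was 0.151 (-0.016 to 0.317), an interval that holds both 0 and the full value, so low array quality and age cannot be told apart here. Age stays open as untested.

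The third pattern is the 2290 probe sets between unimpaired and impaired learners with array weights. Of 100 splits over all animals, which ignore the uneven runs, 2 gave as many. The highest other gave 3218, and why it did was not tested. When learning class was traded only within runs, 14 of 100 splits gave as many, with 4539 the highest other, so chance cannot be excluded once the runs are kept, and uneven runs could be the source. Low array quality stays open. The median ratio of unweighted differences without the arrays of low correlation to weighted differences with all arrays was 0.617 (0.139 to 0.938). This ratio mixes the effect of the weights with that of leaving arrays out. Learning class stays open as untested.

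For the other counts by the same splits, the probe set that passed between unimpaired learners and controls was matched by 2 of 100 splits. The real count was 1 and the highest other 1144, for a reason that was not tested. Within runs the real count was matched by 2 of 100 (highest other 1). A count of 1 is too small for these splits to decide, and the call was lost with the run as a block (smallest adjusted p = 0.0569, and 0.000369 to 0.536 over 34 alternatives), so chance is not excluded. For the 5 comparisons with a real count of 0, 100 of 100 splits gave as many, as any split must, so these splits test nothing. Their highest other counts were 506 for unimpaired against impaired, 1 for young hidden platform, 0 for young and 2321 for aged swimming animals and 1200 for the interaction. With array weights, 8 of 100 splits matched the 1266 of age (highest other 3499) and 21 the 384 of unimpaired against controls (highest other 4820), so chance cannot be excluded for either.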

How the results depend on the processing

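The tests without arrays of low correlation, with the log2 median signal, with weights fitted gene by gene, with the beta-actin ratio and with pairs of settings were chosen after the data were seen. Where a value moved, the cause was not tested unless stated.

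For age (34), quantile normalization gave 18, array weights 1266, weights gene by gene 1274, the run as a block 87, the Gapdh covariate 54, CA1 and choroid plexus covariates 161, the log2 median signal 76, unadjusted p of 0.005 231 and no training covariate 62. Hidden platform animals alone gave 1, the other training groups 0 and cage animals 0, with fewer samples. Limits on correlation of 0.5, 0.85 and 0.88 gave 20, 21 and 6. Quantile normalization with limits of 0.5 and 0.85 gave 13 and 15, and the block with 0.1 and 0.8 gave 106 and 9. Leaving out 1 of 18 animals in turn gave 13 (aged cage D099) to 57 (young yoke D023).

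For unimpaired learners against controls (1), array weights gave 384, weights gene by gene 336 and unadjusted p of 0.005 32. By limma the count was 0 (416 at an unadjusted p under 0.05 in the reported fit) with quantile normalization, no filter, the filter at the percentile 60, the block, CA1 and choroid plexus covariates, controls weighted equally, impaired learners left out, intermediate learners added, and limits of 0.7, 0.85 and 0.88. It was also 0 with quantile normalization and limits of 0.1, 0.5, 0.8 or 0.85, and with the block and 0.1 or 0.8. The probe set that passed in the reported fit lay under the percentile 60, so it was not tested with that filter. Leaving out 1 animal in turn gave 1 to 1.

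For unimpaired against impaired learners (0), array weights gave 2290, weights gene by gene 2192 and unadjusted p of 0.005 191. A limit of 0.5 gave 1 (Fbxl20). The count was 1 (Ntrk3) with limits of 0.7, 0.8 and 0.85, with quantile normalization and 0.85, with the block and 0.8, and with the log2 median signal and 0.8. Unadjusted p of 0.005 gave 4 for young hidden platform (Slc6a6, Rgs16, Klhl2 and 1 probe set without a gene), 22 for young and 9 for aged swimming animals, and 46 for the interaction. The limit of 0.88 gave 1 in young swimming animals (Arf2). In aged swimming animals, CA1 and choroid plexus covariates and the log2 median signal gave 1 each (without a gene), weights gene by gene 4, quantile normalization with 0.85 gave 1 (Pced1b) and the block with 0.8 gave 2 (Gemin7 and 1 without a gene). Leaving out 1 animal in turn gave 0 to 0 for the comparisons with a count of 0, and 0 to 1 for aged swimming animals (Tbcb, without aged cage D098). The genes named here were picked after their values were seen.

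The number of list calls over the 7 comparisons was 20, against 0 with an estimated correlation and 12 with quantile normalization. The oxidative phosphorylation list in aged swimming animals turned direction with the run as a block (adjusted p = 0.906, 2.98e-07 to 0.906 over 8 alternatives). Over all alternatives, 94 of 165 list calls kept direction and threshold, 70 kept direction only and 1 reversed. Of 902 values of named genes that passed, 613 kept both, 289 kept direction only and 0 reversed. These genes and lists were chosen because they passed on the same arrays, so kept direction is largely set in advance. The 902 values include the fits that left out 1 animal in turn, which change the data little.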

Other observations

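The settings without the 14 arrays, and the tests of the oxidative phosphorylation list, were chosen only after the results were seen, and the genes named here were picked after their values were seen.

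Some values between aged and young animals differed once the 14 arrays of low correlation were left out. The complement gene C3 was then higher by 0.70 ± 0.13 (SE, adjusted p = 0.00141), against 0.28 with all arrays (adjusted p = 0.607). The microglia and phagocyte genes had a median of 0.17 and an adjusted p of 0.00308 there. With all arrays this list did not pass (adjusted p = 0.133, and adjusted p = 0.458 with an estimated correlation), and 8 alternatives gave 0.00308 to 0.918, the highest with the run as a block. The MHC and interferon genes had a median of 0.14 and an adjusted p of 0.00462 there. With all arrays they did not pass (adjusted p = 0.298, and adjusted p = 0.632 with an estimated correlation), and with the run as a block their direction turned (adjusted p = 0.59, with 0.00462 to 0.632 over 8 alternatives). In the same setting Marcksl1, a substrate of protein kinase C found in developing neurons, was lower at -0.39 (adjusted p = 0.0222), Tfrc, the transferrin receptor, at -0.44 (adjusted p = 0.0159) and Ptn, a growth factor, at -0.51 (adjusted p = 0.0464). With all arrays these were -0.33 (adjusted p = 0.127), -0.26 (adjusted p = 0.554) and -0.21 (adjusted p = 0.726), and did not pass.

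The mean of the oxidative phosphorylation list relative to all genes in aged animals was 0.104 (-0.026 to 0.249) with all arrays and 0.031 (-0.076 to 0.141) without the 14 arrays. The value without the 14 arrays lay under 0.052, the bound set for a source in low array quality. Its interval holds both 0 and the full value, so low array quality and age cannot be told apart here. With the run as a block the value over all arrays was 0.152.

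A score was used to ask whether unimpaired learners are less aged in expression. It held the 100 genes with the smallest p for age in animals that were not trained on the hidden platform. No probe set passed for age in those animals alone, so these genes were not shown to change with age there. The mean of the score was -0.03 ± 0.54 (SD, n = 14) in unimpaired, 0.40 ± 0.38 (SD, n = 14) in intermediate and -0.36 ± 0.63 (SD, n = 10) in impaired learners. In young hidden platform animals it was -0.18 ± 0.58 (SD, n = 9), above that of the impaired learners. The difference between unimpaired and impaired learners was 0.328 (-0.12 to 0.78, permutation p = 0.182, two-sided), and in the second run 0.3 (5 against 8 animals, exact permutation p = 0.249). The score differed between aged and young hidden platform animals by 0.226 (permutation p = 0.301), so it did not separate the ages in these animals and the test does not decide the question.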
